A study of Mus musculus with 6 samples.

How the data were processed

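Messenger RNA was measured by poly(A)-selected, paired-end sequencing of wild-type mouse chondrocytes, the cells that make cartilage matrix, in 6 libraries. Per the labels' protocols, RNA was extracted with Trizol, checked on a Bioanalyzer, captured on oligo-dT beads, fragmented, reverse-transcribed and sequenced on an Illumina NovaSeq instrument. That protocol speaks of RNA of a specific adipose type, whereas the source is given as chondrocytes, so its text may not have been written for these samples. The series compares chondrocytes with chondrocytes that had received transplanted mitochondria, and its title names osteocytes as their origin. The libraries fall into 2 groups of 3. The sample labels contradict each other about which group is which: the samples whose description reads mAC_Mito carry a title and a treatment entry of vehicle, and the samples whose description reads mAC carry a title and a treatment entry of mitochondria. Both sets of labels split the libraries identically. The groups are therefore called mAC_Mito and mAC after the description field, which is also how the columns of the data table are named, every difference is mAC_Mito minus mAC, and no direction is given as an effect of mitochondria.

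The authors deposited 1 table of 26969 Ensembl genes with 2 values per library. The first is the raw read count per gene, deposited by the authors without normalization, per the file headers. The second is FPKM, the count per kilobase of gene model scaled to the depth of the library, which the authors computed and deposited, per the file headers. Dividing counts by FPKM gave the same gene length in every library to within a ratio of 1.0189 for 99% of 13002 genes, after 1 factor per library. The submitters' processing notes name HISAT2 2.0, StringTie 1.3.0, Bowtie 0.12.2 and the mouse build mm8, without saying what each was used for. The coordinates in the table are those of a later build: of 26902 gene identifiers shared with the GENCODE M21 annotation of GRCm38, 24147 had the same chromosome, start and end and 26821 (99.7%) shared at least 1 end. Positions are printed as the table gives them, on GRCm38. The counting rule, its use of strand and its treatment of reads that fit several genes are not given in the sources used here, so overlapping genes, antisense genes and near-identical copies cannot be separated with certainty.

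Groups were compared on the deposited counts with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 17645, and libraries were scaled by TMM. P-values were two-sided and adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. Standard errors and 95% intervals of log2 fold changes are those implied by the quasi-likelihood F statistic. The design written before the data were examined used limma on log2(FPKM + 1) and named the edgeR test as its replacement should the table hold raw counts, which it does; limma 3.58.1 and DESeq2 1.42.0 are among the alternatives. Nothing in the labels says that the replicates came from separate cultures or animals, so p-values measure the spread between these samples, which may be technical. No pair of libraries agreed within sampling noise: the chi-square per degree of freedom between libraries was 22.1 or more.

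Gene lists (42, covering cartilage, mitochondria, metabolism, stress, cell cycle, signalling, other cell types and RNA quality) were fixed before the data were examined, as were the groups, the tests and most of the alternatives. For each list the members past the threshold were counted, with adjustment over all genes tested and adjusted over the list alone. Lists with at least 5 tested members were also compared with all other genes by camera (limma) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 41 lists tested; camera with an estimated correlation and fry, which asks whether a list's genes move one way without setting them against other genes, were run beside it. The level of a list in a library is the mean, over members, of log2 CPM minus the mean of the 6 libraries. It was compared between groups by a two-sided exact permutation test, which cannot go below 0.1 with 3 against 3 libraries.

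Named genes were chosen by a rule written before the data were examined. It takes (a) among genes with adjusted p under 0.05, mean FPKM of at least 5 in a group, no overlap between the groups and a symbol that is not a predicted or cDNA name, the 10 with the highest and the 10 with the lowest log2 fold change; (b) always Col2a1, Acan, Sox9, Col10a1, Mmp13, Adamts5, Prg4 and Col1a1; (c) for each list up to 2 members that rose and 2 that fell with the smallest adjusted p, or, where none passed, the member with the highest mean FPKM. No gene met part (a). A gene that the rule takes is not reported here. All other genes named in the text, such as Fn1, Mki67, Xist and H19, were chosen after their values were seen.

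Each step was tested on simulated counts drawn from the means and library sizes of these libraries, with 50 genes changed at each fold size. Only genes with a mean of at least 5 CPM were changed, so recovery of rarer genes was not tested. For mAC_Mito against mAC, edgeR recovered 2% of genes changed 1.2-fold, 46% at 1.5-fold, 90% at 2-fold and 100% at 4-fold, with 17212 genes tested. It also called 10 unchanged genes, against 37 for DESeq2 and 8 for limma on log2(FPKM + 1). In the same simulation a list of 30 genes lowered 1.2-fold gave a camera p of 1.71e-12 with the preset correlation and 0.00131 with an estimated correlation. Genes were drawn independently there. The simulation therefore does not test the preset correlation for lists whose members vary together, such as G2/M and mitosis (estimated correlation 0.204). Library totals ran from 59116068 to 68378213 counts, so counting error was small for all but rare transcripts. Limits from a count of 0 use a floor of 3 counts per library and cover counting error only. The alternatives changed the count test, the filter, the scaling, the FPKM pseudocount (0.5 or 0.1 in place of 1), the limma settings, a replicate block and each library in turn. With a library left out the low-count filter was run anew, so the tested members of a list could change. Figures were drawn with matplotlib 3.10.9.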

Results

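Gene expression was profiled in 6 libraries of mouse chondrocytes, 3 in the group described as mAC and 3 in the group described as mAC_Mito. Total counts were 59116068, 68378213 and 62406047 in mAC 1, 2 and 3 and 63700612, 60151766 and 61353072 in mAC_Mito 1, 2 and 3. Between 21437 and 22107 genes had at least 1 count in a library. The most abundant transcript of the nuclear genome was the imprinted non-coding RNA H19, with 1.917% to 2.95% of counts, and Col2a1, the main collagen of cartilage, took 1.052% to 1.729%. The comparison asks how the transcriptome of chondrocytes differs once mitochondria have been transplanted into them. Because the description labels name mAC_Mito as the group with mitochondria and the titles and treatment entries name mAC, the values below give the difference between the groups and not the direction of an effect.

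The cartilage genes did not separate the groups. Col2a1 was at 1117 ± 101 FPKM in mAC and 1390.3 ± 384 FPKM in mAC_Mito (SD, n = 3), a log2 fold change of 0.29 with a standard error of 0.17. Acan, the core protein of the cartilage proteoglycan aggrecan, was at 75.1 ± 9.24 and 103 ± 36.1 FPKM. Sox9, the transcription factor that maintains chondrocyte identity, was at 20.3 ± 2.71 and 22.4 ± 2.83 FPKM. Col1a1, the fibrous collagen of bone and fibroblasts, was at 346 ± 62.9 and 494 ± 196 FPKM. In mAC_Mito, Col2a1, Acan and Col1a1 were lowest in library 1 (951, 63.5 and 271 FPKM), below every mAC library, and higher in libraries 2 and 3 (1662 and 1559, 134 and 113, 634 and 579 FPKM) than in every mAC library, so that the spread within that group exceeded the difference between the groups. Col10a1, the collagen of hypertrophic cartilage, was at 13.9 ± 1.12 and 15.1 ± 1.67 FPKM, and Prg4, which encodes the joint lubricant lubricin, at 25.0 ± 10.5 and 23.6 ± 4.15 FPKM. The collagenase Mmp13 was at 52.3 ± 2.37 and 47.0 ± 3.43 FPKM and the aggrecanase Adamts5 at 3.27 ± 0.556 and 3.52 ± 0.768 FPKM. For all 8 genes edgeR's quasi-likelihood test gave a Benjamini-Hochberg adjusted p of 0.99992, and each 95% interval of the log2 fold change included 0, the widest bounds being -0.75 (Prg4) and 1.06 (Col1a1). Their positions are chromosome 15, 97975602 to 98004695 for Col2a1, chromosome 7, 79053483 to 79115099 for Acan, chromosome 11, 112782224 to 112787760 for Sox9 and chromosome 11, 94936224 to 94953042 for Col1a1. Col10a1 lies on chromosome 10 at 34389981 to 34397085, Prg4 on chromosome 1 at 150449412 to 150466165, Mmp13 on chromosome 9 at 7272514 to 7283331 and Adamts5 on chromosome 16 at 85856173 to 85901828.

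**Figure D1:**
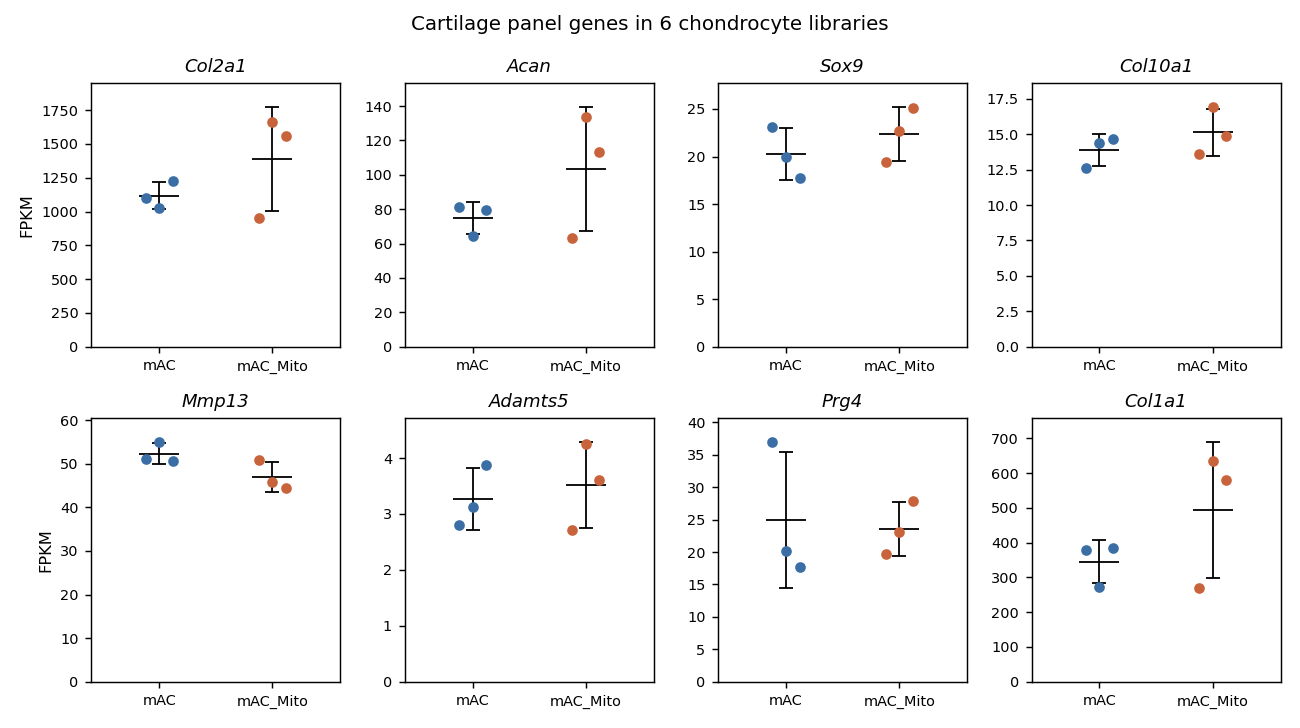
FPKM of the 8 panel genes in each library (points; blue mAC, orange mAC_Mito), with the mean and SD of 3 libraries per group; each vertical axis starts at 0. The groups overlap for every gene, and mAC_Mito 1 lies below the other mAC_Mito libraries for Col2a1, Acan and Col1a1.

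Across the transcriptome 2 of 17645 genes passed an adjusted p of 0.05, 1 higher and 1 lower in mAC_Mito. Both are predicted loci, named here after their values were seen. Gm49890 (ENSMUSG00000117123), a long non-coding RNA on the minus strand of chromosome 4 at 88909855 to 88938521, had no count in any mAC library and 172, 130 and 210 counts in mAC_Mito 1, 2 and 3. This is at least 58.1-fold higher in mAC_Mito, taking a floor of 3 counts per library (edgeR adjusted p = 0.0109). The microRNA gene Mir31 lies inside it and had 1 count in each library. Gm49909 (ENSMUSG00000117098), on the minus strand of chromosome 17 at 70974119 to 71002208, was at 71.3 ± 59.6 FPKM in mAC and 0.357 ± 0.196 FPKM in mAC_Mito (SD, n = 3). Its log2 fold change was -7.63 with a standard error of 0.75 (edgeR adjusted p = 0.0183). It overlaps Myl12a and Myl12b on the same strand, a neighbouring pair of genes for myosin regulatory light chains, so its counts depend on how shared reads were assigned. Its own counts in mAC ranged from 2652 to 11797. Neither gene passed when mAC_Mito 1 or mAC_Mito 3 was left out, or without a filter on low counts, and Gm49909 did not pass without mAC_Mito 2. Leaving out mAC 3 or mAC_Mito 2 gave 3 genes higher and 1 lower. Scaling log2(FPKM + 1) by TMM or by quantiles in limma gave 1 gene higher and 0 lower.

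None of the remaining genes passed an adjusted p of 0.05. The next lowest adjusted p was 0.99992. At an unadjusted p under 0.05 there were 563 genes, 3.19% of those tested, 371 higher and 192 lower. The libraries of the groups did not overlap for 693 genes higher and 773 genes lower in mAC_Mito, together 8.31% of genes, where chance gives 10%. DESeq2 called 2 genes higher and 2 lower, and limma on log2(FPKM + 1) called 1 and 1. The median absolute log2 fold change was 0.12, and for genes with at least 5 CPM the median 95% interval reached 0.28 to either side. On the first principal component, with 27.5% of the variance, the scores were -51.1, -5.3 and 28.9 in mAC 1, 2 and 3 and -21.2, 32.8 and 15.9 in mAC_Mito 1, 2 and 3, so the groups were interleaved.

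Among the gene lists, those of the cell cycle separated the libraries by group. The 28 genes of G2/M and mitosis were lower in mAC_Mito by a mean of 1.17-fold (mean log2 fold change -0.23), with 27 members below 0 (camera adjusted p = 2.89e-19). With an estimated correlation the adjusted p was 0.446. No member passed with adjustment over all genes, 3 were lower in mAC_Mito adjusted over the list alone, and 12 had an unadjusted p under 0.05. Those 3 were Ect2 and Birc5, which act in cytokinesis and chromosome segregation, and the spindle checkpoint kinase Bub1, named after their values were seen. Ect2 was at 10.6 ± 0.34 FPKM in mAC and 8.36 ± 0.346 in mAC_Mito, Bub1 at 9.06 ± 0.4 and 7.17 ± 0.385, and Birc5 at 18.0 ± 0.948 and 14.4 ± 0.941 (SD, n = 3). Cdc20, the list's most abundant member and an activator of the anaphase-promoting complex, was at 50.1 ± 7.24 and 44.3 ± 4.51 FPKM, and the proliferation marker Mki67 at 14.9 ± 3.0 and 14.4 ± 1.02 FPKM. The mean level of the list was 0.225, 0.086 and 0.035 in mAC 1, 2 and 3 and -0.089, -0.109 and -0.147 in mAC_Mito 1, 2 and 3 (exact permutation p = 0.1, the smallest that 3 against 3 allows). The 29 genes of DNA replication and S phase were lower by a mean of 1.07-fold (mean log2 fold change -0.10), with 24 members below 0 (camera adjusted p = 4.4e-05). The adjusted p was 0.446 with an estimated correlation. No member of it passed with either adjustment. Pcna, the sliding clamp of DNA polymerase, was at 70.6 ± 6.37 and 64.9 ± 2.23 FPKM. Counted over all lists, 4 members passed adjusted over the list alone, a number that was 0 without mAC 1 or mAC_Mito 3, 1 without mAC 2, 17 without mAC 3 and 20 without mAC_Mito 1. With the preset correlation, both lists stayed past the camera threshold with each library left out in turn. For the mitosis list, camera with that preset was also run with 3 libraries mixed from both groups against the other 3. Its unadjusted p then ran from 2.25e-08 to 0.651, against 7.04e-21 for the real groups. A small camera p therefore does not by itself speak for a difference between the groups. The 24 genes of p53, senescence and growth arrest had a mean log2 fold change of 0.04 (camera adjusted p = 0.659).

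Lists of matrix genes beyond those of cartilage itself were higher in mAC_Mito. The 27 matrix proteases and inhibitors were higher by a mean log2 fold change of 0.13, with 20 members above 0 (camera adjusted p = 0.00857). With an estimated correlation the adjusted p was 0.595. Timp1, an inhibitor of matrix metalloproteinases and the most abundant member, was at 1076 ± 84.5 FPKM in mAC and 947 ± 96.7 in mAC_Mito, opposite to the list. The 24 genes of fibroblastic and dedifferentiation matrix were higher by a mean log2 fold change of 0.17, with 18 members above 0 (camera adjusted p = 0.00189). The adjusted p was 0.595 with an estimated correlation. The groups overlapped in the level of this list. It was 0.041, -0.162 and -0.136 in mAC 1, 2 and 3 and -0.09, 0.173 and 0.173 in mAC_Mito 1, 2 and 3. Sparc, a collagen-binding protein and its most abundant member, was at 1718 ± 105 and 1631 ± 54.7 FPKM, and fibronectin (Fn1) at 622 ± 114 and 912 ± 316 FPKM. No member of either list passed with adjustment over all genes or adjusted over the list alone. The fibroblastic call was lost without mAC 3 (adjusted p = 0.078), and the protease call without mAC 3 (0.0813) or mAC_Mito 3 (0.117). The protease call was also lost among the 15 members with FPKM of at least 5 in at least 3 libraries (mean 0.073, adjusted p = 0.154). The 30 cartilage genes had a mean log2 fold change of 0.03 (camera adjusted p = 0.747), with 15 members above and 15 below 0, and the 21 tested genes of hypertrophy and mineralisation one of 0.09 (adjusted p = 0.645). Neither sign was stable. The cartilage mean was -0.0042 without mAC_Mito 2 and 0.08 without mAC_Mito 1. The hypertrophy mean was -0.025 without mAC 3, where 22 members were tested, and -0.011 over 11 members with FPKM of at least 5. In both hypertrophy fits the members changed, so they do not show that the sign turns with a library. Spp1, the bone matrix protein osteopontin, was the most abundant gene of the latter, at 2343 ± 177 and 2079 ± 116 FPKM.

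The 13 mRNAs encoded by the mitochondrial genome varied more between libraries than between groups. They took 7.31%, 4.71% and 3.13% of counts in mAC 1, 2 and 3 and 5.6%, 2.91% and 3.4% in mAC_Mito 1, 2 and 3. As a list they were lower in mAC_Mito by a mean log2 fold change of -0.32, with all 13 below 0 (camera adjusted p = 0.00195). With an estimated correlation the adjusted p was 0.805, and without mAC 1 the mean turned to 0.038 (camera adjusted p = 0.835). The call was also lost without mAC_Mito 2 (mean -0.14, adjusted p = 0.252) or mAC_Mito 3 (-0.24, 0.0559), and the mean was -0.66 without mAC 3 and -0.60 without mAC_Mito 1. mt-Co1, a subunit of cytochrome oxidase, was at 9651 ± 2871 and 8099 ± 2631 FPKM (SD, n = 3). Reads of these genes can also fit nuclear copies, of which Gm28661 on chromosome 1 had 132105 to 336246 counts per library. The nuclear genes of respiration gave mean log2 fold changes of 0.03 for the 37 of complex I (camera adjusted p = 0.811) and 0.04 for the 41 of complexes II to V (0.747). Both lists were called lower without mAC 1 (means -0.11 and -0.099, adjusted p = 6.92e-05 and 4.19e-05) and higher without mAC 3 (0.15 and 0.14, 0.000337 for both). Their most abundant members, Ndufa4 and Cox6a1, were at 88.5 ± 18.3 and 90.8 ± 9.23 FPKM, and at 252 ± 40.2 and 254 ± 22.8 FPKM. The camera adjusted p was 0.811 for the TCA cycle, 0.403 for glycolysis, 0.747 for fatty acid oxidation and peroxisome, 0.747 for mitochondrial biogenesis, fusion, fission and mitophagy, 0.456 for the mitochondrial ribosome and import, and 0.987 for mitochondrial protein stress. The list of mitochondrial ribosome and import, with a mean of -0.014, was called lower without mAC 1 (-0.096, adjusted p = 0.00039). No member of these mitochondrial and metabolic lists passed with adjustment over all genes or adjusted over the list alone. Ldha, which makes lactate, was at 597 ± 68.5 and 549 ± 19.4 FPKM, the mitophagy receptor Bnip3 at 126 ± 8.15 and 120 ± 5.78, and the mitochondrial chaperone Hspa9 at 167 ± 14.3 and 166 ± 10.5.

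Immune lists moved in opposite directions. The 29 tested inflammatory cytokines and NF-kB targets were lower in mAC_Mito by a mean log2 fold change of -0.09, with 17 members below 0 (camera adjusted p = 0.0208). The adjusted p was 0.446 with an estimated correlation. The call was lost without mAC 3 (0.207) or mAC_Mito 1 (0.357), where the mean was -0.0077 and -0.033. Without mAC 2 the mean was -0.15. These fits tested 30 members, so a change of members and the removal of a library cannot be told apart in them. Over the 29 members the level was 0.036, -0.043 and 0.146 in mAC 1, 2 and 3. In mAC_Mito 1, 2 and 3 it was -0.063, -0.021 and -0.055. Ptgs2, the inducible cyclooxygenase, was at 25.1 ± 2.59 and 19.4 ± 2.05 FPKM and the neutrophil chemokine Cxcl5 at 13.7 ± 0.714 and 11.1 ± 0.588 (SD, n = 3), both chosen after their values were seen. Cxcl12, the most abundant member, was at 61.3 ± 5.08 and 62.7 ± 1.68 FPKM. The 39 interferon-stimulated genes were higher by a mean log2 fold change of 0.29, with 35 members above 0 (camera adjusted p = 4.4e-05). With an estimated correlation the adjusted p was 0.685. mAC_Mito 3 set this difference: its mean level was 0.587, against -0.23 to -0.045 in the other 5 libraries, and without it the mean log2 fold change was 0.064 (camera adjusted p = 0.565). The macrophage and leukocyte markers stood apart in that library too, at 0.522 against -0.363 to 0.085 in the others. Their mean log2 fold change went from 0.18 over 20 members to -0.049 over 21 members without mAC_Mito 3. Among interferon-stimulated genes and inflammatory genes with FPKM of at least 5 in at least 3 libraries neither call held (7 genes, mean 0.059, adjusted p = 0.542, and 13 genes, mean -0.058, 0.419). B2m, the light chain of MHC class I and the most abundant member, was at 775 ± 167 and 733 ± 199 FPKM. No member of either list passed with adjustment over all genes or adjusted over the list alone.

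On log2 CPM of all 6 libraries, stress, turnover and signalling lists did not pass the set test over the 17645 genes tested. Camera adjusted p-values were 0.739 for ATF4 targets and the integrated stress response, 0.335 for endoplasmic reticulum stress and secretory chaperones, 0.529 for the antioxidant response, 0.149 for the hypoxia response, 0.682 for cytosolic heat shock, 0.879 for immediate early and handling-stress genes, 0.682 for apoptosis regulators and 0.682 for autophagy and lysosome. Cholesterol biosynthesis gave 0.0754, with 20 of 24 members above 0, the Wnt pathway 0.0506, with 18 of 27 above 0, and the TGF-beta and BMP pathway 0.403. On log2(FPKM + 1) with TMM scaling the cholesterol list was called higher (adjusted p = 0.0457), and among genes with FPKM of at least 5 in at least 3 libraries the cholesterol list was called higher and the hypoxia list lower (0.0486 for both). The cholesterol list was also called higher without mAC 2 (0.0285) and the Wnt list without mAC_Mito 1 (0.044). No member of these lists passed with adjustment over all genes or adjusted over the list alone. The transcription factor Atf4 was at 165 ± 18.9 FPKM in mAC and 167 ± 7.0 in mAC_Mito, the chaperone Hsp90ab1 at 570.3 ± 22.8 and 594 ± 38.0, the ferritin light chain Ftl1 at 992 ± 273 and 1087 ± 134, and the growth factor target Ccn2 at 539 ± 14.2 and 548 ± 29.9 (SD, n = 3).

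Markers of other cell types were measured as lists. The 13 tested skeletal muscle markers were higher in mAC_Mito by a mean log2 fold change of 0.29, with all 13 above 0 (camera adjusted p = 0.000129), and the 9 adipocyte markers by 0.28, with all 9 above 0 (0.00189). The adjusted p was 0.595 with an estimated correlation for both. Both calls were lost without mAC 1 (adjusted p = 0.0689 and 0.13) or mAC_Mito 1 (0.095 and 0.126). The muscle mean was 0.087 over 14 members without mAC 1 and 0.14 over 13 without mAC_Mito 1. It was 0.17 over 14 members both without mAC 2 and without mAC_Mito 3. Where 14 members were tested, a change of members and the removal of a library cannot be told apart. Over the 13 members the level was -0.311, -0.105 and -0.017 in mAC 1, 2 and 3. In mAC_Mito 1, 2 and 3 it was 0.426, -0.234 and 0.242. The adipocyte mean was 0.16 without mAC 1. Mylpf, a light chain of fast muscle myosin, was at 19.8 ± 10.1 and 24.2 ± 1.44 FPKM and the fatty acid carrier Fabp4 at 41.6 ± 11.8 and 48.6 ± 7.96 FPKM (SD, n = 3). The extraction protocol in the labels speaks of RNA of an adipose type, while the source is given as chondrocytes. Markers of osteoblasts and osteocytes, the stated origin of the mitochondria, had a mean log2 fold change of 0.07 over 12 tested members (camera adjusted p = 0.786), with a median of -0.028, and ran from -0.12 to 0.037 with each library left out (12 or 13 members). Of these, Bglap2, an osteocalcin gene with near-identical copies, passed adjusted over the list alone, at 1.37 ± 0.374 FPKM in mAC and 3.37 ± 0.794 in mAC_Mito; it was named after its values were seen. The camera adjusted p was 0.103 for macrophages and leukocytes, 0.298 for osteoclasts, 0.739 for endothelium, 0.9 for synovial and tendon fibroblasts and 0.376 for pericytes and smooth muscle. The macrophage list was called higher without mAC_Mito 2, where 21 members were tested (mean 0.21, adjusted p = 0.0167). The osteoclast mean of 0.26 was 0.16 without mAC 2 or mAC_Mito 1, 0.17 without mAC_Mito 3 and 0.43 without mAC_Mito 2. No other marker passed with either adjustment. The synovial list was the only one past 0.05 in the mixed form of fry, which looks for change in either direction (adjusted p = 4.45e-05), and the directional form of fry called 0 lists, the lowest adjusted p being 0.325. The macrophage lysozyme Lyz2 was at 60.0 ± 10.1 and 73.9 ± 20.1 FPKM and highest in mAC_Mito 3, at 96.4 FPKM. Of the erythroid markers 0 had enough counts to test, Hba-a1 having 0 to 10 counts per library.

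With all 6 libraries, lists that read RNA quality and library preparation did not pass the set test either. Camera adjusted p-values were 0.335 for cytosolic ribosomal proteins, 0.879 for replication-dependent histones, 0.193 for nuclear-retained RNAs and 0.682 for sex-linked transcripts. The ribosomal list, with a mean log2 fold change of 0.06, was called lower without mAC 1 (-0.10, adjusted p = 9.31e-05) and higher without mAC 2 (0.087, 0.0285) or mAC 3 (0.18, 7.14e-07), and nuclear-retained RNAs, with a mean of -0.18, were called lower without mAC 2 (-0.27, 0.0227). No member passed with either adjustment. Transcripts of both Xist (8195 to 11931 counts) and the Y-linked gene Ddx3y (2994 to 4017 counts) were present in every library. In all, 9 of 41 lists passed camera with the preset correlation, 5 higher and 4 lower, and 0 passed with an estimated correlation. The mean level separated all libraries of the groups for 3 lists, G2/M and mitosis, S phase and matrix proteases, which is 7.32% of lists, where chance gives 10%. For 10 lists, among them the cartilage, glycolysis and osteoblast lists, the median and the mean of the members had opposite signs, and for 5 the test and the mean did; none of these lists was called.

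**Figure D2:**
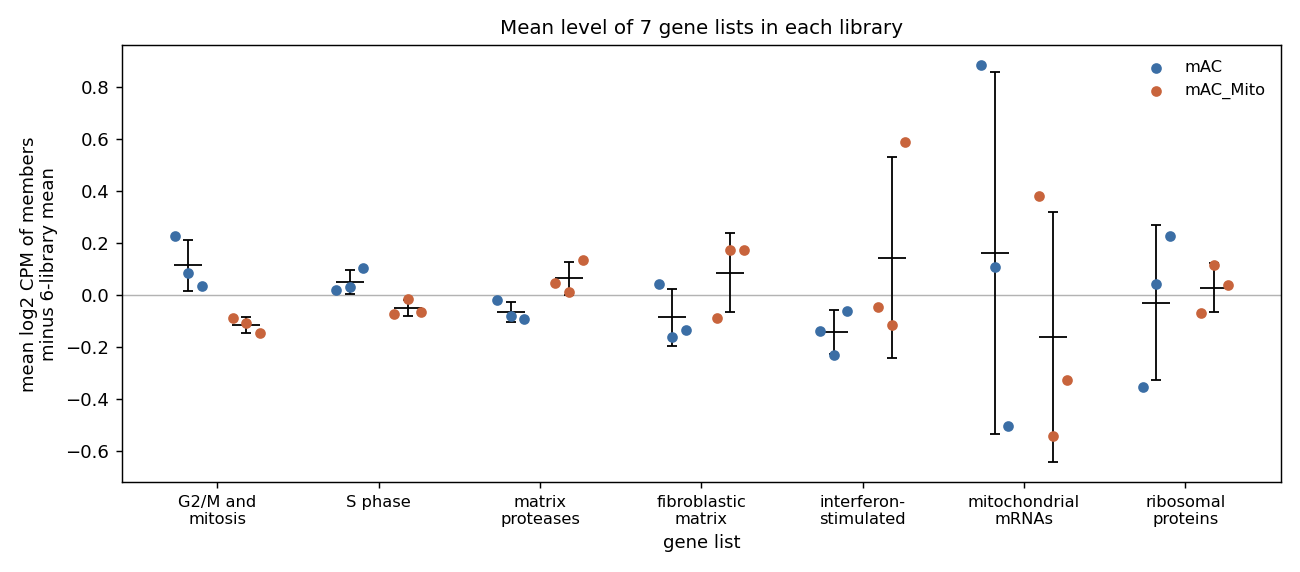
Mean level of 7 gene lists in each library (points; blue mAC, orange mAC_Mito), as log2 CPM of the members minus the mean of the 6 libraries, with the mean and SD of 3 libraries per group. The mitosis, S phase and protease lists separate the groups, mAC_Mito 3 stands apart for interferon-stimulated genes at 0.587, and the mitochondrial mRNAs run from -0.541 to 0.883 in libraries of both groups.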

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

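The robust edgeR fit, the fits without mitochondrial genes and the set test on log2(FPKM + 1) were chosen after seeing the data; the other settings were planned. The counts of 1 gene higher and 1 lower were kept, with Gm49890 and Gm49909 called, by edgeR with DESeq2 size factors, by limma on log2(FPKM + 1), (FPKM + 0.5) or (FPKM + 0.1), by limma without trend or with robust fitting, with a fold threshold and without mitochondrial genes. edgeR without a low-count filter or on genes with FPKM of at least 5, and limma with the same filter or none, gave 0 higher and 0 lower; the latter filter removes Gm49890 from the test. edgeR with robust fitting, and limma with TMM or quantile scaling, gave 1 higher and 0 lower. DESeq2 gave 2 and 2, adding Pnliprp2 and Lrch4. Lrch4 overlaps Gm20605 on its strand, and their summed count was 1741, 2025 and 1376 in mAC and 1846, 1525 and 1952 in mAC_Mito. Gm20605, called without mAC 3, and Dpm1 and Gm20716, called without mAC_Mito 2, also belong to such overlapping pairs. Cpeb4 was called without mAC 3 too, and Gm49510 without mAC_Mito 2. limma with array weights gave 2078 higher and 1627 lower, 251 of them list members (0 otherwise), and turned Prg4 to a called 0.39; its weights ran from 0.218 to 16.8 (mAC 2), so the fit rested on few libraries, and its estimation stopped before convergence. Leaving out each library in turn gave 0 to 3 genes higher (3 without mAC 3 or mAC_Mito 2, 0 without mAC_Mito 1 or 3), 0 to 1 lower, 0 list members throughout and 6 to 12 lists in the set test. Same-numbered libraries deviated with correlations of 0.124, -0.06 and -0.012, within the range of differently numbered ones (-0.14 to 0.154). With so few libraries, pairing by number was neither shown nor excluded. With a replicate block 1 gene was higher, 1 lower, 0 list members passed and 9 lists were called. The 4 members adjusted over the list alone (Ect2, Bub1, Birc5 and Bglap2) did not pass with that block, where the count was 0. It was 17 with DESeq2, 10 with robust edgeR and 2 with limma on log2(FPKM + 1), and 0 to 20 with each library left out.

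Camera called 9 lists with the preset correlation and 0 with an estimated one, the only setting that moved this count beyond 1.5 times. With each library left out, the mean log2 fold change ran from -0.658 to 0.038 for the mitochondrial mRNA list, -0.115 to 0.149 for nuclear complex I, -0.0995 to 0.143 for complexes II to V and -0.102 to 0.185 for ribosomal proteins. Without mAC 1, which had the highest share of mitochondrial counts, the first turned to 0.038 and lost its call, and the others, above 0 with 6 libraries, were called lower; without mAC 3 those 3 lists were called higher (adjusted p = 0.000337, 0.000337 and 7.14e-07), so their call turns with the library removed. On genes with FPKM of at least 5, 7 lists were called: the protease, inflammatory and interferon calls ended, the muscle list had too few members to test, and hypoxia and cholesterol lists were added. The cause was not tested. Over named genes and settings, 1094 values stayed on their side of the threshold or within 1 standard error, 20 moved further, and 18 became and 14 ceased to be called. Depth was not the limit for abundant genes. In simulation 46% of genes changed 1.5-fold and 90% of those changed 2-fold were recovered, all with a mean of at least 5 CPM. There were 10 false calls. Smaller differences, and differences of rarer genes, can be missed. The cause of the other changes between settings was not tested.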

Other observations

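The tests of Gm49890, of dilution by other cells and of Gene Ontology terms were chosen after the result was seen. The others were written down before their own results were seen. Some of them address differences already seen in these data, such as the lower Gm49909 and the lower mitosis list. Gene Ontology terms of 15 to 300 tested genes, as annotated in the table, were compared by camera with the preset correlation. Of 2283 terms, 81 were higher and 18 lower in mAC_Mito. The lowest p-values belonged to kinetochore genes (condensed chromosome kinetochore, 75 of 91 members below 0, adjusted p = 1.7e-05), to collagens and other structural matrix constituents conferring tensile strength (28 of 32 above 0, adjusted p = 1.7e-05) and to initiation of DNA replication (17 of 21 below 0, adjusted p = 4.26e-05). The integrin complex (21 of 25 above 0, adjusted p = 0.000884) and the basement membrane (67 of 94 above 0, adjusted p = 0.000823) were also higher. With an estimated correlation 0 terms passed, the lowest adjusted p being 0.799.

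With 3 against 3 libraries there are 10 splits, too few for a share under 0.05. The real split gave 2 genes and the highest of the others 28, as 3 of 10 splits gave at least 2. For the lists the real split gave 9 and the highest other 11 (5 splits with at least 9), and for the ontology terms 99 and 453 (2 splits with at least 99). The split with 28 genes sets mAC 1, mAC 2 and mAC_Mito 1 against the rest, with 3030 genes at an unadjusted p under 0.05 against 563 for the real split, which points to a structure of the samples that crosses the groups. Genes with no count in 3 libraries and at least 10 in each of the rest, as Gm49890, numbered 3 in the real split and 1 to 6 in the others.

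The genes called are predicted loci, and one technical explanation is that reads of overlapping genes were divided differently from library to library. Genes with a mean count of at least 100 whose replicates in a group differed at least 8-fold overlapped another gene on their strand in 22 of 34 cases, against 16.3% of the other 12974 genes (odds ratio 9.44, Fisher's exact p = 3.45e-10), so read division may account for much of this instability. One of them, Gm20716, held 0% of its sum with Dpm1 in mAC_Mito 1 and 3 and 76.3% to 85.3% in the other 4 libraries, whereas Gm20605, which is not among them, held shares of its sum with Lrch4 that differed by group without overlap (10.1%, 14.4% and 3.56% in mAC, 80.6%, 51.1% and 63.4% in mAC_Mito). For Gm49909 the sum with Myl12a and Myl12b had a log2 fold change of -0.019 (95% interval -0.304 to 0.265), which includes both 0 and the -0.197 that losing Gm49909 reads alone would give, so read division and a loss of the transcript cannot be told apart. For Gm49890 the only overlapping gene on its strand, Mir31, held at most 0.769% of the count needed in any mAC library. This speaks only against a passing of reads to Mir31, which spans 88910557 to 88910662 and had 1 count in each library. A gene so short could take few of the reads, and genes on the other strand were not checked, so the test does not decide on read division. A real difference in this RNA, chance and an assignment to other genes stay open.

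The lower G2/M and mitosis list could reflect chondrocytes diluted by other cells, which would lower cartilage genes as much. It could also reflect the share of mitochondrial RNA. Neither would be a difference in cycling between the groups. The cartilage list differed by 0.033 (SE 0.055) and the mitosis list by -0.23 (SE 0.059), a gap of 0.263 (SE 0.093). As a difference of group means, this argues against dilution as the whole cause. The cartilage level was 0.093 and 0.044 in mAC_Mito 2 and 3. In mAC_Mito 1 it was -0.087, near the mitosis level of -0.089, so for that library dilution stays open. Markers of other cells go the way of dilution in part: skeletal muscle (mean log2 fold change 0.29) and adipocyte markers (0.28) were called higher in mAC_Mito, but not with an estimated correlation (adjusted p = 0.595 for both), without mAC 1 (0.0689 and 0.13) or without mAC_Mito 1 (0.095 and 0.126), and the uncalled osteoclast mean was 0.26 (0.16 to 0.43 with each library left out). The uncalled macrophage (0.18), osteoblast (0.07), endothelial (0.05), synovial (0.04) and pericyte means (0.04) each turned below 0 with at least 1 library left out, and the medians of the osteoblast (-0.028) and synovial lists (-0.061) lay below 0, so these lists show no direction. With the share of mitochondrial counts as a covariate the mitosis difference was -0.191 (SE 0.033), 0.832 of its size, which argues against that share as the whole cause. The mean difference was larger in the real split (0.23) than in any of the 9 others (up to 0.147). That order is fixed once all libraries are apart by group, so it adds nothing to the exact permutation p of 0.1. The 10 splits cannot exclude chance. Differences in culture density or timing, and the group itself, stay open and were not tested.

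Mitochondrial mRNAs and the cytosolic ribosomal proteins varied in opposite directions over the 6 libraries, irrespective of group (Pearson r = -0.935, permutation p = 0.00556, adjusted 0.00925; Spearman rho = -0.886, permutation p = 0.0333, adjusted 0.0444; 4 relations computed). Nuclear complex I gave r = -0.918 (permutation p = 0.00556) and rho = -0.886 (0.0333), complexes II to V r = -0.907 (0.00694) and rho = -0.943 (0.0167), and the fibroblastic matrix list r = -0.228 (0.668) and rho = -0.314 (0.564). Without mAC 1 and mAC_Mito 1, the farthest from the median, r was -0.66, -0.587, -0.5 and -0.504, so the first 3 relations rest largely on those libraries, while the fibroblastic one was weak with all 6. Transcript length and GC content are argued against. The 241 nuclear genes of the same range followed the mitochondrial list with a slope of 0.083 (95% interval -0.062 to 0.228). Leaving mitochondrial genes out of the totals kept 0.905 of the ribosomal range (0.612 of 0.676 log2 units). As these genes took only 2.955% to 7.378% of counts, a large change was not possible. Their counts displacing others therefore account for little of that range. Other effects of library composition were not tested. RNA quality, handling and a difference between cultures stay open, and the labels give no batch to test.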
